A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

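RNA was measured in 7 libraries of Saccharomyces cerevisiae BY4741 in 5 groups: log phase (2 libraries), saturated culture (2), rapamycin for 1 h (1), rapamycin for 4 h (1) and a lawn grown for 3 days (1). The design text speaks of 10 libraries, and the others were not analysed here. Per the labels' protocols, cells grew in synthetic complete medium at 30 °C, total RNA was depleted of ribosomal RNA and fragmented, and short fragments were sequenced as single reads. Per the submitters' processing notes, cutadapt 1.8 and STAR 2.4 were used with the R64 (sacCer3) build. The counting tool, the annotation and whether counting used strand are not given in the sources used here.

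For each library the authors deposited a table of 6665 genes and a table of 300 introns. Per the file headers, both give the read count of each feature, taken as raw counts since the values are whole and sum to different totals. Per the file headers, the same tables give TPM, and the deposited TPM values of genes and introns together sum to 1000000 in each library. TPM served here for densities and intron lengths only. Gene identifiers were matched by locus tag to symbols in a table of the R64 assembly for 5991 genes, and 674 did not match. Host-gene spans come from that table, while the coordinates of introns were not used here.

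Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, in one fit of 7 libraries in 5 groups, with TMM scaling, the low-count filter of edgeR (5827 genes tested) and Benjamini-Hochberg adjustment at 0.05, two-sided. The fit had 2 residual degrees of freedom and 6.94 prior ones, so every condition with 1 library takes its spread from the log-phase and saturated pairs. An intron relative to its host was tested by one edgeR fit over gene and intron columns of each library (terms for library, kind of column and kind by group), for introns with at least 10 reads in 1 or more libraries: 270 tested, 30 not. In this fit the prior degrees of freedom were infinite, meaning that the spread was pooled fully across introns, and limma 3.58.1 on log2 ratios with a pseudocount of 0.5 was run as an alternative. Intron level alone was tested with edgeR, scaled by gene reads. That measure, the contrast of genes between both rapamycin times, the setting of no change in the median intron and that without 8 introns that hold small nucleolar RNA genes were chosen after seeing the data. Plain library totals for genes and the settings applied to intron level were likewise added later. The other settings for gene and intron comparisons were chosen before the data were examined, while the tests of explanations were written later, some of them after the result was seen.

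Gene lists, 34 in number, were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation and fry, with Benjamini-Hochberg adjustment over lists. With an estimated correlation, camera takes its p-values from the 2 residual degrees of freedom of the fit. Few lists can pass on so few, so a call lost there is not evidence against a list. The text names, for saturated cultures, the 10 largest rises and 10 largest falls past the threshold with a standard symbol, a mean of at least 10 CPM and the same direction in both pairs of libraries with the same number (the fits used no pairs), and the 6 largest each way in other conditions. It also names up to 4 members of each list by size of change, the largest changes among introns by the same kind of rule, and ECM33 and ACT1 always. Counting intervals are exact at 95%, and the floor for a gene without reads was 3 reads in the library. Values after ± on a log2 scale are standard errors.

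Depth ran from 1019287 to 9438379 gene reads per library. Between log-phase replicates the counts differed by more than sampling noise (chi-square per degree of freedom 16.1), as did those of saturated replicates (35.9), so neither pair is one library given a second time. This does not show that they came from separate cultures. The steps were tested on simulated data with 200 changed genes and a dispersion of 0.05. A 4-fold change was recovered for 93.9% of changed genes in saturated cultures (5801 genes fitted), 89.4% at 4 h of rapamycin (5795), 83.3% at 1 h (5799) and 86.4% in the lawn (5776), a 2-fold change for 29.9%, 11.9%, 11.9% and 19.4%. For introns relative to host, an 8-fold change was recovered for 100%, 100%, 100% and 90% in the same order (273, 275, 272 and 270 introns), and a 4-fold change for 90%, 70%, 45% and 70%. Changed genes and introns were drawn only from those above a minimum mean of reads, with 20 introns per fold. Recovery for introns with few reads was therefore not tested. In the saturated simulation (5770 genes) camera found the 1 raised list and called 0 of 33 others, while fry missed the raised list. Genes were simulated independently, whereas the ribosomal protein list had an estimated correlation of 0.71. False calls on lists whose genes move together were therefore not tested.

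Alternatives were DESeq2 1.42.0 size factors and its Wald test (its adjusted p was missing for 2 named results, which were left out), plain totals, other filters on low counts, a minimum fold, fits on the log-phase and saturated libraries alone, each replicate left out in turn, and a block for the replicate number.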

Results

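RNA levels of genes and of introns were measured in 7 libraries of the budding yeast Saccharomyces cerevisiae, strain BY4741, a haploid laboratory strain of mating type a that lacks several nutritional genes. Total RNA depleted of ribosomal RNA was fragmented and sequenced, so that intron RNA was read along with messenger RNA. Log-phase cultures (2 libraries) were harvested at an OD600 of 0.5, and saturated cultures gave 2 libraries. Log-phase cells moved to fresh medium with 100 nM rapamycin, an inhibitor of the TOR growth-signalling kinase, gave 1 library after 1 h and 1 after 4 h. Cells grown for 3 days as a lawn on plates gave 1 library. Gene reads numbered 6714865 and 1875036 in log phase, 4665149 and 1019287 in saturated cultures, 9438379 at 1 h of rapamycin, 6781835 at 4 h and 1312256 in the lawn. Introns took 1.28% and 1.33% of all reads in the log-phase libraries and 2.90% and 2.46% in the saturated ones. The share was 0.826% at 1 h of rapamycin, 1.56% at 4 h and 2.60% in the lawn. These shares include introns that hold small nucleolar RNA genes, where mature small nucleolar RNA may be counted. That of ASC1 alone had 15761 reads in log phase and 23273 in saturated cultures. All introns together had 86996 and 25347 reads in the log-phase libraries and 139090 and 25677 in the saturated ones. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counting intervals cover counting error only.

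The comparison of saturated with log-phase cultures asked which introns are more abundant when growth stops. The intron of ECM33 (YBR078W), which encodes a cell-wall protein, gave 212 ± 26.6 reads per 100 host-gene reads in saturated cultures (SD, n = 2) and 1.87 ± 0.161 in log phase (SD, n = 2). Relative to its host gene the ECM33 intron rose by a log2 value of 6.83 ± 0.32 (SE), and its level alone rose by 4.69, while ECM33 mRNA fell by 2.19 ± 0.42. The intron of SAC6 (YDR129C), which encodes the actin-bundling protein fimbrin, went from 0.359 ± 0.157 to 29.7 ± 1.00 reads per 100 host reads, and that of RFA2 (YNL312W), a subunit of the replication protein A complex, from 1.42 ± 0.0647 to 89.2 ± 5.72 (SD, n = 2 each). The second intron of EFM5 (YGR001C) had 160 reads in the saturated libraries and 1 in log phase, a ratio relative to host reads of 351 with a counting interval of 62.2 to 13968.5. In genome build R64 these hosts span 393123 to 394742 on chromosome II for ECM33, 713340 to 715379 on chromosome IV for SAC6, 48287 to 49216 on chromosome XIV for RFA2 and 497133 to 498034 on chromosome VII for EFM5. Their introns are 330, 111, 108 and 93 nt long.

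Of 270 introns tested, 216 rose and 3 fell relative to their host gene in saturated cultures, with a median log2 change of 2.21 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The intron of SAR1, a secretory GTPase, rose by 5.18 ± 0.47 and that of RPS6B by 5.16 ± 0.33. Other large rises came from introns of ASC1 (6.38 ± 0.39), TEF4 (6.28 ± 0.34), RPL7A (second intron, 5.99 ± 0.34) and IMD4 (5.76 ± 0.32), which hold the small nucleolar RNA genes SNR24, SNR38, SNR39 and SNR54, so reads of the mature small nucleolar RNA may be counted there. Few log-phase reads stood behind the introns of GIM5 (19 reads against 1, ratio 116, counting interval 18.4 to 4814), KEI1 (24 against 3, 40.1, 12.2 to 208), YPR170W-B (77 against 2, 37.6, 10.1 to 316), DID4 (37 against 2, 35.9, 9.25 to 307) and LSM7 (37 against 2, 30.8, 7.94 to 264). The introns of YLR202C (−1.66 ± 0.66), SNR17B (−1.57 ± 0.48) and MRK1 (−1.54 ± 0.58) fell relative to host, but without log-phase replicate 1 the value for MRK1 was 1.45. The intron of ACT1 (YFL039C, chromosome VI, 53260 to 54696), the actin gene, went from 1.09 ± 0.166 to 4.55 ± 0.388 reads per 100 host reads, a log2 change of 2.02 ± 0.35 (edgeR, Benjamini-Hochberg adjusted p = 2.47e-08). With the median intron set to no change, a setting chosen after seeing the data, 67 introns rose and 34 fell beyond it. ECM33 stood 4.56 ± 0.28 above that median, and ACT1 lay at −0.22 ± 0.30 (edgeR, Benjamini-Hochberg adjusted p = 0.579).

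**Figure D1:**
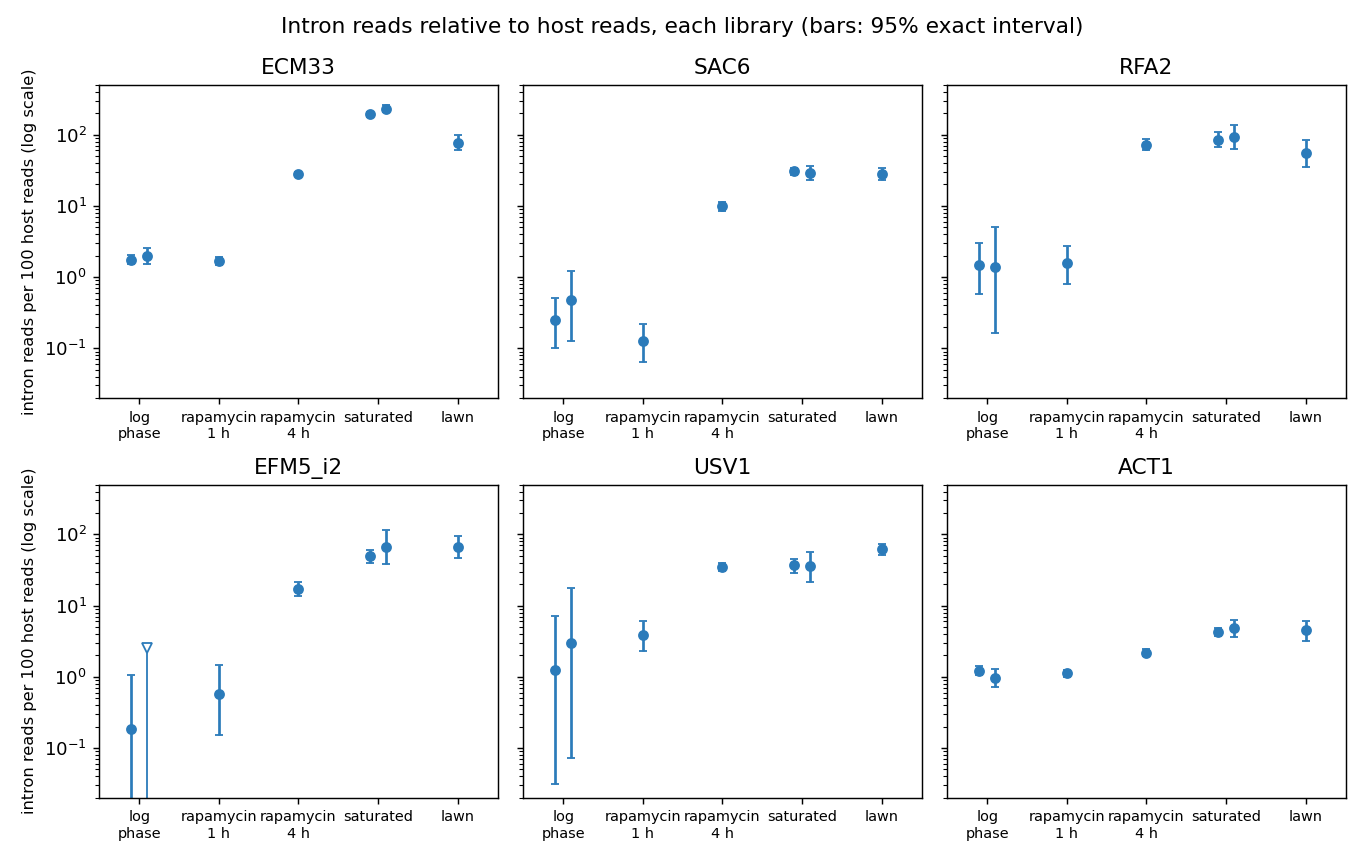
Intron reads per 100 host-gene reads (log axis) for the introns of ECM33, SAC6, RFA2, EFM5 (second intron), USV1 and ACT1 in each group, with a point per library, bars for its exact 95% counting interval and an open triangle for the upper limit of a library with 0 reads. The ECM33 intron lies near 1.87 in log phase and 1.70 at 1 h of rapamycin, and at 27.9, 77.5 and 212 at 4 h of rapamycin, in the lawn and in saturated cultures.

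A change relative to host can come from the host or from the intron, and both differed between ribosomal protein genes and other genes. Level here is relative to the gene reads of a library, not an amount per cell. In saturated cultures the host fell for 103 of 104 ribosomal protein introns (median −2.84), a host with 2 introns being counted once for each. The level of these introns themselves rose for 10 and fell for 34 (median −0.39). These counts were 3 and 9 without log-phase replicate 1, 3 and 19 without log-phase replicate 2, 7 and 53 without saturated replicate 1, and 24 and 45 without saturated replicate 2. Among the 166 introns of other genes, level alone rose for 117 and fell for 1 (median 2.36). The host, again counted for each intron, rose for 53 and fell for 35 of the 165 with a tested host. Relative to host, 103 of 104 ribosomal protein introns rose against 113 of 166 others (Fisher's exact test, two-sided, p = 4.06e-12, Benjamini-Hochberg adjusted over 4 conditions p = 5.42e-12). The median rise was close in both classes, 2.23 and 2.15, and among introns with at least 50 reads the others had the higher one (2.56 against 2.23). With that minimum 103 of 104 ribosomal protein introns and 55 of 71 others rose, so the shares also depend on read depth. By level alone, a measure added after seeing the data, the order turned, with 10 of 104 against 117 of 166 (Fisher's exact test, two-sided, p = 2.16e-24, adjusted p = 8.65e-24). Introns are not independent replicates, so these tests describe these libraries.

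**Figure D2:**
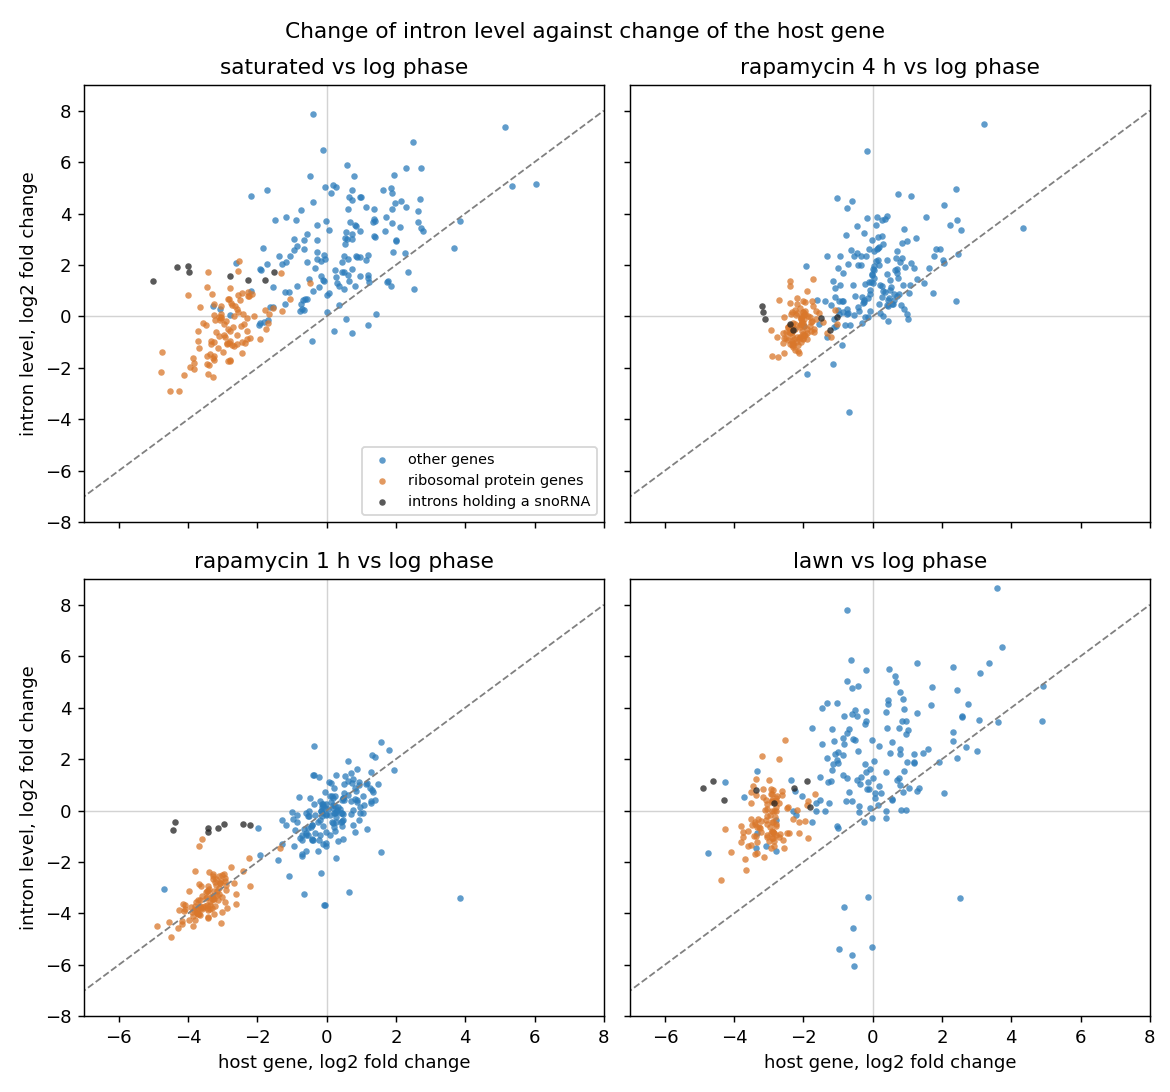
Log2 change of intron level (vertical axis) against log2 change of the host gene (horizontal axis), each relative to log phase, in 4 panels, with a point per intron, separate colours for introns of ribosomal protein genes, of other genes and with a small nucleolar RNA, and a dashed line of equal change. Over all 104 ribosomal protein introns, those with a small nucleolar RNA included, hosts centre on −2.84 with introns at −0.39 in saturated cultures. At 1 h of rapamycin the same medians are −3.41 and −3.45.

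The rapamycin libraries asked whether inhibiting TOR changes introns in the same way, early and late. At 4 h, 173 introns rose and 2 fell relative to host, with a median of 1.55. The RFA2 intron rose by 5.62 ± 0.59, SAC6 by 4.99 ± 0.48 and ECM33 by 3.91 ± 0.37, and ACT1 rose by 0.98 ± 0.40 (edgeR, Benjamini-Hochberg adjusted p = 0.0223). The intron of USV1, a zinc-finger transcription factor gene (YPL230W), had 400 reads at 4 h and 2 in log phase, a ratio relative to host reads of 19.8 with a counting interval of 5.44 to 164, and the second EFM5 intron had 103 against 1 (117, 20.6 to 4685). The introns of SNR17B (−3.09 ± 0.71) and MRK1 (−1.89 ± 0.60) fell, although MRK1 gave 1.10 without log-phase replicate 1. By level alone, 55 introns rose and 4 fell. The risers numbered 11 without log-phase replicate 1. Of 104 ribosomal protein introns 2 fell in level, but 0 did when log-phase replicate 1 or log-phase replicate 2 was left out, and 45 when saturated replicate 1 or saturated replicate 2 was. Beyond the median intron, 26 rose and 10 fell. Calls from a single library assume that it varies like the log-phase and saturated pairs, with no replicate check.

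After 1 h of rapamycin the introns of ECM33 (−0.13 ± 0.37, edgeR, Benjamini-Hochberg adjusted p = 0.931) and ACT1 (0.01 ± 0.39, adjusted p = 0.998) did not pass the test. Of 270 introns, 12 rose and 5 fell relative to host, with a median of −0.11. Of the 6 introns with the largest rises, 5 hold small nucleolar RNA genes, led by NOG2 with SNR191 (3.91 ± 0.42) and IMD4 with SNR54 (3.72 ± 0.36). The other was RPL34A (2.52 ± 0.39). Over the 270 introns, limma on log ratios called 7 higher. Without the 8 introns that hold such genes, a setting chosen after seeing the data, 4 introns rose in the edgeR fit. By level alone the 6 had log2 values between −1.11 for RPL34A and −0.46 for NOG2. The introns of MRK1 (−3.89 ± 0.76) and SNR17A (−3.65 ± 0.81) fell; the gene span of SNR17A overlaps IRC13, whose reads cannot be told apart without stated strand. REC114 had 0 intron reads against 2 in log phase. Ribosomal protein introns fell in level at 1 h, 99 of 104 with a median of −3.45. The host fell for 103 of the 104, with a median of −3.41. Other introns fell in level for 8 and rose for 3 of 166, with 0 risers without log-phase replicate 2, 1 without log-phase replicate 1, and 6 and 5 without saturated replicates 1 and 2. The fallen numbered 3 without log-phase replicate 1. The lone 1 h library is assumed to vary like the pairs.

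Tested directly, 4 h differed from 1 h of rapamycin in 169 introns relative to host, of which 167 were higher at 4 h (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and limma on log ratios called 81. SAC6 was higher by 6.28, RFA2 by 5.49 and ECM33 by 4.03. Against saturated cultures, 70 introns were lower and 0 higher at 4 h of rapamycin, with a median of −0.68. At an unadjusted p under 0.05, 95 introns differed in either direction, limma called 13, and 35 differed without saturated replicate 1. ECM33 was lower at 4 h than in saturated cultures by a log2 value of −2.92 ± 0.35 and the second EFM5 intron by −1.65 ± 0.46. Both rapamycin contrasts compare a single library with others, under the same assumption on its spread.

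In the lawn, 186 introns rose and 2 fell relative to host, with a median of 2.35. Beyond the median intron, 43 rose and 30 fell. The SAC6 intron rose by 6.49 ± 0.48 and reached 28.1 reads per 100 host reads, ECM33 rose by 5.38 ± 0.42, and ACT1 by 2.02 ± 0.48 (edgeR, Benjamini-Hochberg adjusted p = 5.87e-05). The introns of IMD4 (5.79 ± 0.42) and TEF4 (5.78 ± 0.42), which hold small nucleolar RNA genes, rose as their hosts fell (−4.90 and −4.62), and by level alone neither passed (0.87 and 1.14, edgeR, Benjamini-Hochberg adjusted p = 0.135 and 0.0988). The second EFM5 intron had 56 reads against 1 (ratio 454, counting interval 78.2 to 18248), and that of YPR170W-B had 15 against 2 (55.2, 12.8 to 498). The second intron of YOS1 rose by 5.63 ± 0.81. SNR17B had 1 intron read against 67 (ratio 0.12, counting interval 0.00299 to 0.692), and MRK1 fell by 1.49 ± 0.59 but stood at 1.51 without log-phase replicate 1. By level alone 68 introns rose and 8 fell, and 43 rose without log-phase replicate 1. Of 104 ribosomal protein introns 7 fell in level, but 1 did without log-phase replicate 1, 2 without log-phase replicate 2, and 43 when saturated replicate 1 or saturated replicate 2 was left out. With plain library totals, 103 rose in level. ECM33 mRNA fell by 4.26 ± 0.62, and the level of its intron (1.12) did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.160). ACT1 mRNA fell by 2.21 ± 0.46, and its intron stood at −0.17 in level. Against saturated cultures, 2 introns were higher and 3 lower in the lawn. Without saturated replicate 1 a single intron differed, and 3 did when log-phase replicate 1 or log-phase replicate 2 was left out. The lone lawn library is assumed to vary like the pairs.

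Introns of ribosomal protein genes rose relative to host more often than other introns at 4 h (100 of 104 against 73 of 166, Fisher's exact test, two-sided, p = 5.01e-21, adjusted p = 2.00e-20) and in the lawn (102 against 84, p = 2.01e-19, adjusted p = 4.01e-19), but not detectably at 1 h (6 against 6, p = 0.545 before and after adjustment). All 104 ribosomal protein introns reached 50 reads in a library, against 71 of the 166 others, so more of the others were hard to call. Among introns with that minimum the medians were 1.76 and 1.52 at 4 h and 2.61 and 2.35 in the lawn. By level alone the order turned at 4 h (2 against 53, Fisher's exact test, two-sided, p = 6.68e-11) and in the lawn (5 against 63, p = 6.56e-11), each with an adjusted p = 8.90e-11. The ribosomal protein risers by level at 4 h numbered 0 when log-phase replicate 1 or log-phase replicate 2 was left out and 4 when saturated replicate 1 or saturated replicate 2 was, and those of other genes 11 without log-phase replicate 1. In the lawn the ribosomal protein risers numbered 1 when log-phase replicate 1 or log-phase replicate 2 was left out and 8 without saturated replicate 2, and those of other genes 42 without log-phase replicate 1. The host fell for 100 of 104 ribosomal protein introns at 4 h and for 104 of 104 in the lawn. Introns risen in both saturated cultures and 4 h of rapamycin numbered 170, where independent lists give 138.4 and simulated unchanged groups 0. Saturated cultures and the lawn shared 182 (148.8 for independent lists), 4 h of rapamycin and the lawn shared 164 (119.2), and 162 rose in all 3 conditions. The covariance of log2 changes was 1.60, 2.38 and 1.81 for these pairs, against 0.136, 0.151 and 0.133 in 20 simulations of unchanged groups. Unchanged groups leave few introns to call, so their simulated overlap of 0 does not bear on the excess over independent lists. Each part of a split log-phase pair would keep 1 library, so the pair was not split, and part of the excess may come from these shared controls.

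Among genes, saturated cultures had far more RNA of HSP30, a membrane heat-shock protein (log2 10.44 ± 0.64), PDC5, a pyruvate decarboxylase (9.93 ± 0.67), THI4, a thiamine synthesis enzyme (9.38 ± 0.56), NRS1 (9.60 ± 0.52), EGO4 (8.70 ± 0.73), the cell-wall genes PIR3 (8.35 ± 0.58) and SPI1 (8.33 ± 0.61), and HSP26, a small heat-shock protein (8.14 ± 0.74). HHY1 had 123 reads against 1 in log phase (ratio 229, counting interval 40.3 to 9103) and RRT1 had 413 against 3 (256, 87.0 to 1246). The largest falls were of RPL9A (−6.01 ± 0.44), INA1 (−5.98 ± 0.45), UTR2 (−5.56 ± 0.40), the mitotic cyclin CLB2 (−5.53 ± 0.37), the hexose transporter HXT2 (−5.39 ± 0.40), the CTP synthase URA7 (−5.26), the chitin synthase CHS2 (−5.06 ± 0.33), ASC1 (−5.00) and RPS9B (−4.78 ± 0.43). Of 5827 genes tested, 1626 rose and 1460 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 2 each). With plain library totals 1225 rose and 1833 fell, as the median of all genes moved from 0.10 to −0.21. Without log-phase replicate 1, 1990 genes changed in place of 3086. RPL9A, RPS9B, PDC5 and other genes with a near-identical copy may have exchanged reads with it in counting, as may overlapping and antisense genes.

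Growth genes fell in saturated cultures. Ribosomal protein genes fell for 135 of 137 with 1 risen (median −2.93; RPL22A −4.75 ± 0.34, RPS22A −4.59 ± 0.37), ribosome biogenesis genes for 62 of 68 (GAR1 −3.62 ± 0.39, NOP58 −3.42 ± 0.32), translation factors for 30 of 37 (TEF4 −4.34 ± 0.36) and RNA polymerase I and III subunits for 13 of 19 (RPA43 −4.34 ± 0.38). Adjusted over the list alone, 135, 64, 31 and 13 fell, with 1 ribosomal protein gene and 1 polymerase gene risen. Their camera calls were lost with an estimated correlation (limma, Benjamini-Hochberg adjusted p = 0.455 with an estimated correlation for each). That setting rests on 2 residual degrees of freedom, on which few lists can pass, so such a loss does not count against a list. Genes of G1/S and replication fell for 27 of 32 (28 adjusted over the list alone; CLB6 −5.02 ± 0.68, RNR1 −4.07 ± 0.33), those of G2/M for 14 of 20 with 2 risen (15 and 2 adjusted over the list alone; CLB1 −3.26 ± 0.39) and those of ergosterol synthesis for 17 of 23 (17 adjusted over the list alone; ERG6 −3.69 ± 0.32, ERG13 −3.59 ± 0.30). These camera calls were also lost (limma, Benjamini-Hochberg adjusted p = 0.455 with an estimated correlation).

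General stress genes rose for 30 of 44 (31 adjusted over the list alone; median 2.33; SSE2 5.42 ± 0.53), stationary-phase genes for 12 of 17 (12 adjusted over the list alone; SNZ1 5.65 ± 0.43), autophagy genes for 21 of 29 with 1 fallen (22 and 1 adjusted over the list alone; ATG1 3.13 ± 0.40, ATG31 1.88 ± 0.35) and targets of nitrogen catabolite repression for 20 of 35 with 3 fallen (21 and 3 adjusted over the list alone; PUT1 7.51 ± 0.40, MEP2 5.48 ± 0.51). Methionine and sulfur genes rose for 15 of 23 with 3 fallen (15 and 3 adjusted over the list alone, STR3 5.29 ± 0.47). The 3 genes listed here as low-affinity hexose transporters, HXT3 (4.63 ± 0.45), HXT4 (3.16 ± 0.40) and HXT1 (2.74 ± 0.34), all rose (3 of 3 adjusted over the list alone). For each of these lists the camera call was lost (limma, Benjamini-Hochberg adjusted p = 0.455 with an estimated correlation). Of 34 lists, camera called 13 up and 11 down with a preset correlation, and 0 with an estimated one. Under the estimated one 1 list had an unadjusted p under 0.05, and fry called 18. Some lists lost their call although the estimated correlation was below the preset 0.01, as for ergosterol synthesis (−0.034). Its unadjusted camera p went from 4.3e-08 to 0.026. Such a loss goes with the 2 residual degrees of freedom of that setting and does not come from correlation between genes. The setting therefore does not show which calls depend on correlation. Splicing factors rose for 15 and fell for 9 of 66 (12 and 8 adjusted over the list alone) and were not called by camera (limma, Benjamini-Hochberg adjusted p = 0.859). The helicases PRP43 (−3.75 ± 0.30) and SUB2 (−2.18 ± 0.31) fell, and MUD1 rose (1.96 ± 0.29). Markers of meiosis and sporulation rose for 11 and fell for 1 of 24 (11 and 1 adjusted over the list alone; SPS100 6.82 ± 0.86, MND1 6.05 ± 0.45), and mating type a markers fell for 6 of 7 (6 adjusted over the list alone; BAR1 −3.78 ± 0.39). These calls were lost too (limma, Benjamini-Hochberg adjusted p = 0.455 and 0.472 with an estimated correlation).

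**Figure D3:**
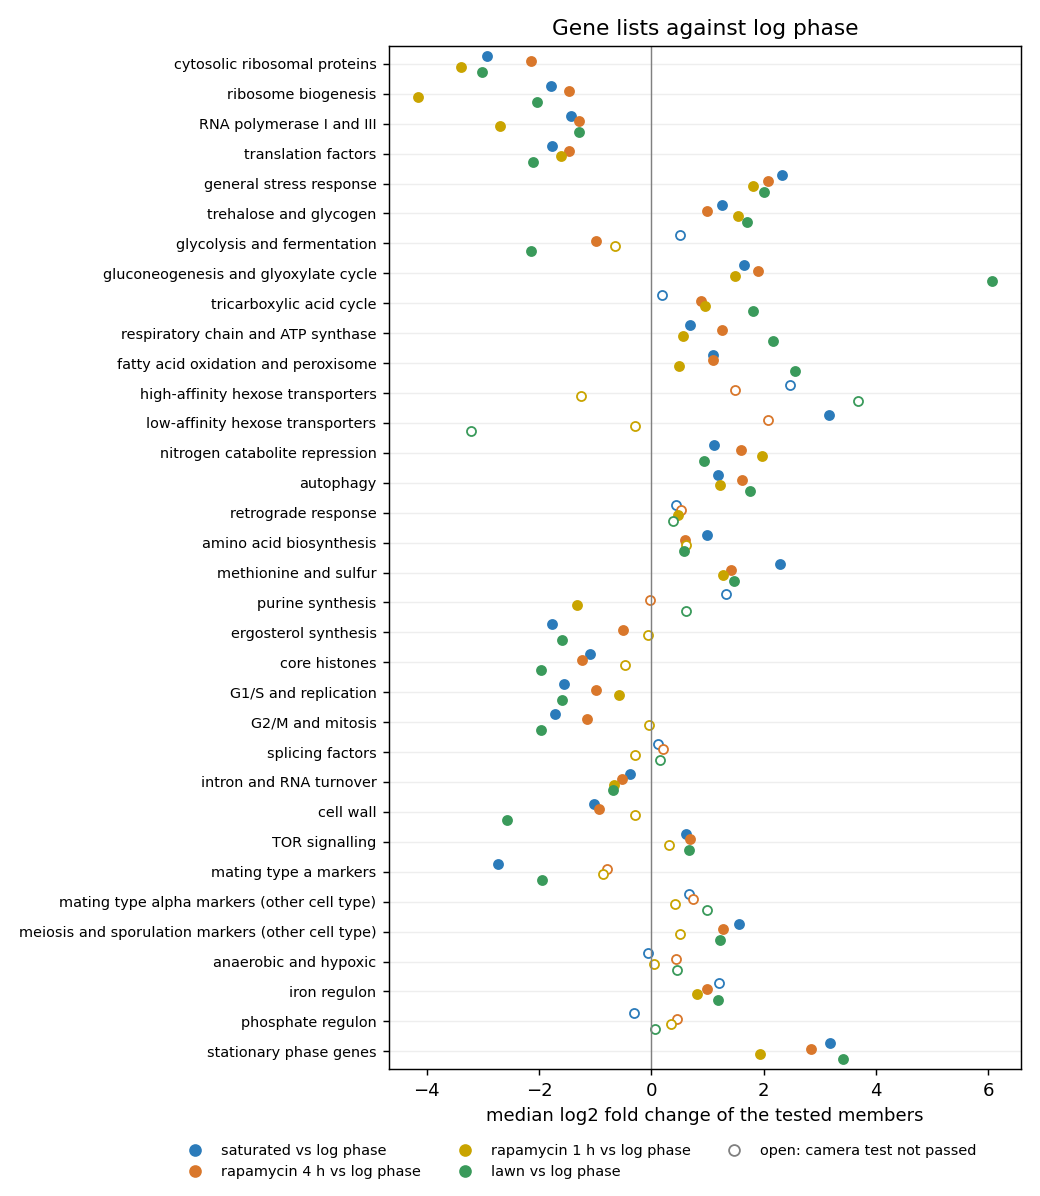
Median log2 change of each of 34 gene lists relative to log phase (horizontal axis), with 1 line per list and a point per condition, filled where camera called the list at its preset correlation, calls that were lost with an estimated one. Ribosome biogenesis lies at −4.16 at 1 h of rapamycin against −1.79 in saturated cultures, and gluconeogenesis reaches 6.06 in the lawn.

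At 1 h of rapamycin, genes that make ribosomes fell together. All 68 ribosome biogenesis genes tested fell (median −4.16; the nucleolin NSR1 −5.53 ± 0.44, the helicase HAS1 −5.11 ± 0.42, the GTPase NOG1 −5.07 ± 0.47), as did 135 of 137 ribosomal protein genes (median −3.39) and 18 of 19 subunits of RNA polymerase I and III (RPA135 −4.97 ± 0.49). Adjusted over the list alone, 68, 136 and 19 fell, with 1 ribosomal protein gene risen. Their camera calls were lost (limma, Benjamini-Hochberg adjusted p = 0.481 with an estimated correlation for each). Purine synthesis genes fell for 8 of 17 (11 adjusted over the list alone; GUA1 −4.45 ± 0.43, IMD4 −4.45 ± 0.40; limma camera, Benjamini-Hochberg adjusted p = 0.481 with an estimated correlation). URA7 (−5.22 ± 0.41), RKI1 (−5.08 ± 0.44) and RMT2 (−5.05 ± 0.48) fell as well. Nitrogen catabolite repression targets rose for 24 of 35 (27 adjusted over the list alone), among them the ammonium permease MEP2 (5.07 ± 0.53) and the allantoate permease DAL5 (4.94 ± 0.39), with an adjusted p = 0.444 with an estimated correlation (limma camera, Benjamini-Hochberg). DAL80, a repressor of that regulon, had 1148 reads against 1 (ratio 850, counting interval 152 to 33604). INO1 (5.49 ± 0.35), GDH3 (5.19 ± 0.57) and NRS1 (6.06 ± 0.55) rose. In all, 535 genes rose and 673 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), against 919 and 590 with plain library totals, which moved the median gene from 0.04 to 0.32. Without log-phase replicate 1, 734 genes changed in place of 1208, and without saturated replicate 1 or 2, which set the spread, 2285 or 2271 did. Camera called 12 lists up and 7 down, 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05, and fry called 5.

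At 4 h of rapamycin the fall of ribosomal protein genes took in 131 of 137 (135 adjusted over the list alone; median −2.14; RPS22A −3.40 ± 0.47) and that of ribosome biogenesis genes 53 of 68 (62 adjusted over the list alone; NOP1 −2.87 ± 0.49). Both camera calls were lost (limma, Benjamini-Hochberg adjusted p = 0.416 with an estimated correlation). Respiratory chain and ATP synthase genes rose for 29 of 40 (34 adjusted over the list alone; NDE2 5.74 ± 0.46, QCR10 2.42 ± 0.38), autophagy genes for 21 of 29 (23 risen and 1 fallen adjusted over the list alone; ATG39 4.44 ± 0.33) and general stress genes for 28 of 44 (34 adjusted over the list alone; HSP26 6.63 ± 0.72). Again the calls were lost (limma camera, Benjamini-Hochberg adjusted p = 0.392, 0.416 and 0.474 with an estimated correlation). PIR3 (128-fold) and SHH3 (6.79 ± 0.43 on the log2 scale) rose, and few log-phase reads stood behind DAK2 (996 reads against 3, ratio 332, counting interval 113 to 1615), DAL80 (280 against 1, 280.4, 49.9 to 11113), ISF1 (400 against 2, 200.3, 55.1 to 1659) and DPA10 (212 against 1, 212, 37.7 to 8423). The acetaldehyde dehydrogenase ALD6 (−4.60 ± 0.82), the cell-wall genes CWP1 (−4.57 ± 0.57) and UTR2 (−4.10 ± 0.47), RPL9A (−4.20 ± 0.54) and the phosphatase PHO3 (−3.99 ± 0.64) fell. Altogether 863 genes rose and 669 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), against 1284 and 423 with plain library totals, which moved the median gene from 0.06 to 0.39. Plain totals also ended the call for ECM33 mRNA (−1.94 ± 0.54, edgeR, Benjamini-Hochberg adjusted p = 0.0284). Without log-phase replicate 1, 688 genes changed in place of 1532, and without saturated replicate 1 or 2, 2764 or 2734 did. Camera called 14 lists up and 11 down, 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and fry called 2. Between 4 h and 1 h, a comparison added after seeing the data, 308 genes were higher and 57 lower at 4 h, and 1408 or 1387 differed without saturated replicate 1 or 2. NSR1 was higher at 4 h by 3.47, and INO1 differed by −5.84.

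Lawn cells had more RNA of genes for using carbon sources other than glucose. Gluconeogenesis and glyoxylate cycle genes rose for 17 of 20 (17 adjusted over the list alone; median 6.06), with the succinate-fumarate carrier SFC1 at 8.77 ± 0.48, malate synthase MLS1 at 8.36 ± 0.71 and the lactate permease JEN1 at 8.34 ± 0.55. Respiratory chain and ATP synthase genes rose for 38 of 40 (39 adjusted over the list alone; NDE2 6.68 ± 0.47, COX7 3.55 ± 0.33) and fatty acid oxidation genes for 17 of 22 (17 adjusted over the list alone; POT1 7.16 ± 0.87). Each camera call was lost (limma, Benjamini-Hochberg adjusted p = 0.376 with an estimated correlation). Glycolysis genes fell for 14 and rose for 1 of 21 (14 and 3 adjusted over the list alone; ENO2 −4.91 ± 0.70, HXK2 −4.33 ± 0.52), and this call was lost as well (limma camera, Benjamini-Hochberg adjusted p = 0.487 with an estimated correlation). Ribosomal protein genes fell for 136 of 137 (136 adjusted over the list alone; median −3.01) and cell-wall genes for 25 of 37 with 2 risen (25 and 2 adjusted over the list alone; CIS3 −5.64 ± 0.69), both with an adjusted p = 0.376 with an estimated correlation (limma camera, Benjamini-Hochberg). SIP18 (9.71 ± 0.67), SPG4 (8.70 ± 0.58) and ECM13 (8.55 ± 0.45) rose. DPA10 had 278 reads against 1 (ratio 1341, counting interval 239 to 53149) and ISF1 249 against 2 (600.5, 165 to 4986). GIC1 had 0 reads against 209, at least 14.3-fold lower from a floor of 3 reads in the lawn library. UTR2 (−6.00 ± 0.56), INA1 (−5.93 ± 0.61), ELO3 (−5.51 ± 0.52) and HXT1 (−5.26 ± 0.55) fell. The test called 1204 genes higher and 1218 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjustment), against 1772 and 870 with plain library totals, which moved the median gene from 0.04 to 0.47. Without log-phase replicate 1, 1553 genes changed in place of 2422. Camera called 14 lists up and 12 down, 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and fry called 20. As for rapamycin, the lone library is assumed to vary like the pairs. Median, mean and test differed in sign for a few lists that camera did not call: tricarboxylic acid cycle (median 0.20, mean 0.05, test down) and phosphate regulon (−0.30, 0.19, down) in saturated cultures, ergosterol synthesis (−0.05, 0.05, up) at 1 h, and purine synthesis (0.62, −0.44, up) and anaerobic genes (0.46, −0.17, up) in the lawn.

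Genes deleted in BY4741 checked the strain. LEU2 had 1 read in all 7 libraries together, MET17 had 16 (12 of them in saturated replicate 1) and URA3 had 51, of which 44 lay in the library of 4 h of rapamycin. HIS3, which is only partly deleted in this strain, had 6612. The U3 small nucleolar RNA genes SNR17A and SNR17B together took 0.731% of gene reads in log-phase replicate 1 and 0.946% in replicate 2, against 3.87% and 2.48% in saturated replicates 1 and 2. SNR17A rose there by 2.35 ± 0.50 (edgeR, Benjamini-Hochberg adjusted p = 0.00407).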

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

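The tests of unspliced host RNA, of scaling and of single-library variation were chosen only after the result was seen; those of genomic DNA and paralogs were written before. Differences between the rapamycin times were tested directly (edgeR quasi-likelihood, Benjamini-Hochberg adjustment), and each gene and intron listed in the next paragraph passed. In all, 169 introns differed relative to host and 365 genes differed.

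The log2 difference of 4 h minus 1 h relative to host was 6.28 for the SAC6 intron, 5.49 for RFA2, 4.82 for the second EFM5 intron, 4.03 for ECM33, 4.03 for YPR170W-B, 3.14 for USV1 and 0.98 for ACT1. It was 5.40 for GIM5 (11 reads against 0) and 6.33 for REC114 (0 reads at 1 h), both fitted values that depend on the prior count and bound nothing. Further introns were higher at 4 h, by 3.01 for SNR17A, 2.00 for MRK1 and 1.14 for TEF4, while NOG2 (−3.19) and the second RPL7B intron (−1.56) were lower. Among genes, DPA10 was higher at 4 h by 6.97, DAK2 by 4.66, ISF1 by 4.48, RMT2 by 3.68, PIR3 by 3.65, NOG1 by 3.61, NSR1 by 3.47, SHH3 by 3.24, HAS1 by 2.60, URA7 by 2.21 and RKI1 by 2.10. INO1 (−5.84), CWP1 (−2.93), UTR2 (−2.79) and DAL5 (−2.75) were lower.

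Ribosomal protein introns recovered in level between 1 h and 4 h, with 99 of 104 higher at 4 h. Their median difference was 3.06, against 1.32 for the 166 other introns, so the shift was not confined to ribosomal protein introns. With plain totals the median for ribosomal protein introns was 3.10. The TMM factors of the 1 h and 4 h libraries were close (1.17 and 1.20). Swapping them for plain totals could thus hardly move the difference, and scaling between libraries was not tested by it. Reads shared between paralogs do not account for the recovery of ribosomal protein introns, as the lower quartile was 2.43 over 7 introns of genes with no A or B partner. Variation between single libraries cannot be told apart from the time on rapamycin, because each time has 1 library. A longer time on the drug stays open as an untested biological explanation.

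In saturated cultures, 112 introns outside ribosomal protein genes and without a small nucleolar RNA rose in level. All of them (100%) stood at 2 times the 10th percentile of gene TPM or more in both libraries, a bar meant to test for genomic DNA. In saturated replicate 2, however, 742 of the 6665 genes had no reads, so any intron met that bar. These introns were also picked for their rise, so genomic DNA was left untested. With plain totals 103 of them passed, which argues against the choice of TMM over plain totals as the cause. Both scalings are relative to gene reads, so a change of the messenger RNA pool as a whole was not tested. The 8 introns that hold small nucleolar RNA genes were higher in level too, from 1.37 for ASC1 to 1.97 for the second RPL7A intron. Unspliced host RNA that is read evenly along its length cannot raise an intron above the density of its host. Uneven coverage and reads of overlapping genes could, and were not tested. Of 32 introns above the host density in both libraries, 23 also passed a one-sided exact binomial test on pooled reads (Benjamini-Hochberg adjustment). Among them were ECM33 (7.55 and 9.02 times the host density), RFA2 (6.48 and 7.10) and SAC6 (5.29 and 5.04). For 2 of the 23, REC114 and YBR090C, the density was also above that of the host in both log-phase libraries. For the remaining 89, of which 9 were above the host density in both libraries without passing that test, unspliced RNA and excised introns cannot be told apart, since the files used here hold no junction reads. A candidate explanation for the 23, excised introns that outlast their host RNA, was found and tested on the same data, and it is weakest where the density was little above that of the host (UBC4 1.10 and 1.28 times, SUN4 1.55 and 1.28), since the binomial test covers counting error only.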

How the results depend on the processing

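The settings of an unchanged median intron, of no small nucleolar RNA introns, of plain totals for genes, of intron level alone with each setting applied to it, and the gene contrast of 4 h with 1 h were chosen only after the result was seen. Depth limits single introns, since 1 to 3 log-phase reads stand behind several large ratios, and the lone libraries of rapamycin and the lawn have no replicate check. DESeq2 size factors and no filter kept the direction and side of the threshold of the 501 named gene results, as did a mean of at least 1 CPM for the 498 it tested. Leaving out log-phase replicate 1 ended 71 of their calls and turned 1 value, leaving out log-phase replicate 2 ended 43, the DESeq2 Wald test 25 and plain totals 17. For introns relative to host, scaling is absorbed by the library term and tests nothing.

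Left-out replicates gave these ranges: genes changed in saturated cultures 1990 to 3589, at 4 h of rapamycin 688 to 2764, at 1 h 734 to 2285, in the lawn 1553 to 3313, and between 4 h and 1 h 367 to 1408. Introns higher relative to host ranged from 162 to 204 in saturated cultures, 128 to 178 at 4 h, 9 to 12 at 1 h and 160 to 189 in the lawn. Introns differing ranged from 35 to 78 between 4 h and saturated cultures, 152 to 174 between 4 h and 1 h, and 1 to 7 between lawn and saturated cultures. Introns higher in level ranged from 87 to 132 in saturated cultures, 11 to 69 at 4 h, 0 to 6 at 1 h and 43 to 79 in the lawn. Leaving out a saturated library raised the numbers of genes changed at 4 h, at 1 h and in the lawn, and leaving out a log-phase library lowered them. Without a saturated library the spread came from the log-phase pair alone, which differed less (chi-square per degree of freedom 16.1 against 35.9). Without a log-phase library it came from the saturated pair alone. No further cause was tested.

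By level alone, 127 introns rose in saturated cultures, 55 at 4 h, 3 at 1 h and 68 in the lawn, 40 differed between 4 h and saturated cultures, and 0 between lawn and saturated cultures (edgeR; 31 at an unadjusted p under 0.05 relative to host, and 3 by limma). Level alone, which does not take out the change of the host, turned the sign of the share of ribosomal protein introns minus that of others to −60.9 points in saturated cultures, −30.0 at 4 h, −1.81 at 1 h and −33.1 in the lawn. In the same order, the host medians of ribosomal protein introns were −2.84, −2.11, −3.41 and −2.93. Those of other introns were 0.36, 0.04, 0.12 and −0.20. As level holds the change of the host, the fall of ribosomal protein hosts lowers it. At 1 h the difference in shares, not detectable in the first place, also turned with a minimum of 50 reads (−2.68). It turned as well when introns with a log2 change of at least 1 were counted (−3.27). That setting counted 15 of 166 other introns, more than the test called, so it did not keep the adjusted threshold. With the median intron unchanged, 67, 26 and 43 introns rose in saturated cultures, at 4 h and in the lawn. A minimum of 10 reads in every group mean tested fewer introns and left 128 risen in saturated cultures and 111 differing between 4 h and 1 h. Limma on log2 ratios called 7 risers at 1 h, 13 introns between 4 h and saturated cultures and 81 between 4 h and 1 h. Without small nucleolar RNA introns 4 rose at 1 h. Plain totals raised introns higher in level to 7 at 1 h and 103 in the lawn. Gene lists called fell to 0 in each condition with an estimated correlation, and fry called 2 at 4 h and 5 at 1 h. Calls were also lost where the estimated correlation was below the preset 0.01, as for nitrogen catabolite repression at 1 h (−0.0036). The fall to 0 goes with the 2 residual degrees of freedom of that setting and does not measure the effect of correlation alone.

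Reversed by level alone were introns of SNR17B (0.0938) and MRK1 (1.05) in saturated cultures, MRK1 at 4 h (0.61) and in the lawn (3.49), ACT1 in the lawn (−0.17), and at 1 h NOG2 (−0.46), IMD4 (−0.74), ASC1 (−0.69), TEF4 (−0.53), RPL34A (−1.11) and the second RPL7B intron (−0.84). Over left-out replicates the MRK1 intron ranged from −1.88 to 1.45 in saturated cultures, −2.20 to 1.10 at 4 h and −1.80 to 1.51 in the lawn, each high value being without log-phase replicate 1. At 1 h, ACT1 mRNA ranged from −0.0444 (without log-phase replicate 1) to 0.0593, and the ACT1 intron, close to 0, gave −0.121 without log-phase replicate 2.

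The fits did not pair libraries by replicate number, as differences between replicates correlated at 0.19 over genes across the 2 groups; the rule for naming genes did use the numbers. With a replicate block, 8 introns differed between lawn and saturated cultures, 31 rose in level at 4 h, and the ACT1 intron at 1 h stood at −0.0402; the cause was not tested.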

Other observations

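No test in this part was chosen only after its result was seen, though the thiamine genes were listed after PDC5 and THI4 had been seen to rise.

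In saturated cultures other genes of thiamine uptake and synthesis were also higher. Of 16 tested, 10 rose and 1 fell, among them the transporter THI7 (3.54 ± 0.52), THI73 (7.64 ± 0.84), PET18 (3.72 ± 0.49), THI6 (3.33 ± 0.43) and SNZ3 (3.86 ± 1.07), while PHO3, a phosphatase that acts on thiamine phosphates, fell (−1.49 ± 0.43; edgeR, Benjamini-Hochberg adjustment). At 4 h of rapamycin 2 of the 16 rose and 1 fell (median 1.26), at 1 h PHO3 was the 1 gene that passed (median 0.37), and in the lawn 4 rose and 1 fell (median 1.55).

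A hypothesis is that the saturated cultures were short of thiamine. The median log2 change of the other 16 listed genes was 1.70, as such a shortage needs, where 1626 of 5827 genes rose at large. For the same 16 genes, medians of 1.55 in the lawn and 1.26 at 4 h of rapamycin are of similar size. Over the 7 with no near copy the medians differed more. They were 3.33 in saturated cultures, 1.32 in the lawn, 1.14 at 4 h and 0.07 at 1 h. All but the first rest on a single library each, so the shift is not shown to be particular to saturated cultures. The fall of PHO3 and the values of THI11 (−0.25) and THI80 (0.20) do not go with a uniform rise. Reads shared between near copies are argued against, since 7 listed genes with no near copy had a median of 3.33, and 5 of them rose. The medium was not measured, so the shortage itself stays untested.

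Genes of the high-affinity hexose transporter list went apart. In saturated cultures HXT2 fell (−5.39 ± 0.40) while HXT5 (4.02 ± 0.67) and HXT6 (2.87 ± 0.65) rose, and in the lawn HXT2 fell (−5.00 ± 0.52) while HXT5 (7.62 ± 0.80) and HXT6 (7.13 ± 0.61) rose. HXT6 and HXT7 are near-identical, so the value of each is uncertain.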
